A study of Mus musculus with 6 samples.

How the data were processed

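Total RNA of osteoclasts was depleted of ribosomal RNA and made into directional libraries that were sequenced from both ends on an Illumina HiSeq instrument, per the labels' protocols. RAW264.7 cells were given 100 ng/mL RANKL for 5 days. Bacteria (S. aureus) were added to cells at 1 to 10 and left for 2 h, and gentamicin at 100 µg/mL, which acts on those outside the cells, was then given for 1 h, per the labels' protocols. The groups were taken from the titles (3 libraries titled Treat, 3 titled Control). The treatment field reads normal for the Treat libraries and infected for the Control libraries, and the first library of each group, which has no number, was taken as number 1. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

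The tools named per the submitters' processing notes are cutadapt 1.9.3, STAR 2.5.1b, HISAT2 2.0.4, Cufflinks, Cuffdiff 2.2.1 and edgeR 3.16.5, with build mm10. Which tool made which table is not given in the sources used here. FPKM values were computed by the authors per protein-coding gene and per lncRNA transcript, per the file headers. The circRNA table holds whole-number counts of back-splice junction reads per circRNA, deposited without normalization per the file headers. A further set of columns deposited beside the FPKM values, headed as counts, is a signal scaled by a factor per library: the same library differed by a factor of 3.921 between the 2 deposited sheets. In those columns 93.9% to 96.5% of low values lay within 0.05 of a multiple of 1 step per library, and that step, 0.672 to 4.347, was used only to infer the number of mRNA fragments (2113901 to 23330810 per library). Values near 0 were not multiples of the steps, so no count test was run on mRNA or lncRNA. A sheet with 1 Treat and 1 Control library equals the libraries numbered 1 of the 6-library sheet in all 22564 mRNA and 6886 circRNA lines and differs in 11 and 1 of 56347 lncRNA lines. It was used only for this check. The circRNA libraries hold 4221 to 7188 junction reads each, 480 to 5719 of them exonic, which limits the precision of their counts.

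The mRNA table lists 22564 genes under 22481 symbols. The lncRNA table repeats a transcript for each associated gene, and its 56347 lines were reduced to 31549 transcripts and summed to 26306 units by symbol or identifier. A locus on chromosome 19 (5590100 to 6300096) holds 39 listed genes, 30 of them expressed, and all are at 0 in Treat 2, Treat 3 and Control 2. Fau, a ribosomal gene that every cell uses, was listed at 483, 0 and 0 FPKM in Treat 1, 2 and 3 and at 574, 0 and 921 in Control 1, 2 and 3, and Malat1 at 10204, 0 and 0 and at 8787, 0 and 6025. These zeros were read as failed estimates and the locus, which includes Rela, Ehd1 and Neat1, was left out, a rule set after the values were seen. Genes that overlap or have near-identical copies may share fragments in the deposited estimates. Positions given for genes and lncRNAs are those of the deposited locus, which can hold several genes, as the one above does. They can therefore be wider than the feature itself.

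mRNA and lncRNA were tested with limma 3.58.1 in R 4.3.3 (trend and robust moderation) on log2(FPKM + 1), with a mean FPKM over the 6 libraries of at least 1 for mRNA and 0.5 for lncRNA. Fold changes are on this scale, which understates the change of low genes. circRNA counts were tested with the quasi-likelihood test of edgeR 4.0.16 with TMM scaling and the filterByExpr filter (minimum count 10), which left 27 circRNAs, and with DESeq2 1.42.0 as an alternative. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with cameraPR at a preset correlation of 0.01, and with camera at an estimated correlation and fry beside it. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Lists of 3 or more tested genes were used, 21 of 24, and a list of 45 known lncRNAs was looked up apart. KEGG pathways were taken from the pathway column of the deposited mRNA table (15 to 300 tested genes), a step added later. Other values were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

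The groups, tests, filters, gene lists, first set of alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 8 largest rises and 8 largest falls among mRNA genes that pass and whose groups do not overlap (symbols of Gm with digits or ending in Rik skipped), filled up by the smallest unadjusted p where fewer pass. It takes 5 and 5 lncRNAs and circRNAs likewise, up to 4 passing members of each list, or the 2 with the highest level where none passes, and Tnf, Il1b, Cxcl2, Ptgs2, Nfkbia, Ctsk, Acp5, Nfatc1, Mmp9 and Atp6v0d2 always. Since no gene passed without a block, the rule was also applied to the fit with the block. Genes of a count of 5 or fewer, and those named outside the rule, were chosen after their values were seen. Some genes that the rule takes are not reported here.

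Whether the numbers in the titles pair the libraries was checked from the correlation of each library's deviations from its group mean. For the pairs numbered 1, 2 and 3 it was 0.761, 0.464 and 0.451 in mRNA and 0.682, 0.408 and 0.338 in lncRNA, all over 0.1, so the numbers were taken to pair these samples; the pairing comes from the titles and these values, not from a stated batch. Libraries numbered 2 and 3 also correlated across numbers, Treat 2 with Control 3 at 0.311 in mRNA and 0.377 in lncRNA and Treat 3 with Control 2 at 0.342 and 0.314, so that only the pair numbered 1 stood clearly apart. Deviations of 3 libraries from their mean sum to 0, so a pair that stands apart drives the other libraries to 1 side. The check therefore cannot tell whether the libraries numbered 2 and 3 are paired by number, which the replicate block assumes.

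Alternatives covered the pseudocount, the filter, the scaling, the moderation, the block, summing by symbol, the correlation and test of the lists, and each library left out in turn. Others were added after the data were seen and are named as such beside their results.

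The steps were tested on simulated data. Those for mRNA, lncRNA and lists were drawn from the fit with the replicate number as a block, which favours that fit, with genes independent of each other. With 200 of 9975 mRNA genes changed, limma without a block recovered 0%, 21.2% and 78.0% of differences of 1, 2 and 3 (log2), with 0.2% of calls false. With the block it recovered 79.4%, 99.6% and 99.7%, with 9.1% of calls false, above the nominal 5%. For 2867 lncRNA units the shares were 0.1%, 23.4% and 71.1% without a block (0.2% false) and 33.7%, 93.1% and 97.3% with it (6.9% false). For 27 circRNAs with 6 changed they were 7.5%, 40.0% and 75.0% (5.8% false). A list of random genes shifted by 1 was found in 100% of simulations. These hold no correlation between genes, so they do not test the preset correlation of 0.01. In the data the estimated correlations of the lists that passed with the preset ran from 0.087 to 0.751.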

Results

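Protein-coding RNA, long non-coding RNA (lncRNA) and circular RNA (circRNA) were measured in 6 total RNA libraries of osteoclasts, the multinucleate cells that resorb bone. The cells were grown from RAW264.7, a mouse macrophage line that forms osteoclasts when given RANKL, and the question of the study was how the circRNAs of such cells differ when Staphylococcus aureus is inside them. There were 3 libraries titled Treat and 3 titled Control. The treatment field of the labels calls the cells of the Treat libraries normal and those of the Control libraries infected, which contradicts the titles, so groups are named here by title, every difference is Treat minus Control, and infection is read from neither label.

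The libraries numbered 1 stood apart from the others in both groups. The deposited values hold about 2113901 mRNA fragments in Treat 1 and 2968605 in Control 1, against 18967864 and 23330810 in Treat 2 and 3 and 22322063 and 21158661 in Control 2 and 3. Lars2, a gene listed at 5717 and 5589 FPKM (fragments scaled to transcript length and to the number of mapped fragments) in Treat 1 and Control 1, was listed at 5.50 to 7.42 FPKM in the other 4. The first principal component of the mRNA values held 67% of the variance and parted the pair numbered 1 from the rest. Both groups have 1 such library, so values over the libraries numbered 2 and 3 alone are given beside the pooled ones. FPKM values summed to 276905 in Treat 1 and 321461 in Control 1, against 466048 to 485677 elsewhere. With Treat 1 or Control 1 left out, the other one is unmatched, so differences of many genes can shift together. For mRNA, libraries with the same number also varied together, most clearly the pair numbered 1. Whether those numbered 2 and 3 are paired by number could not be told. Results of a fit with the replicate number as a block are given where they differ.

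Genes of inflammation were far higher in the libraries titled Treat. Cxcl2, a neutrophil-attracting chemokine, stood at 433 ± 436 FPKM in Treat and 2.76 ± 0.504 in Control (mean ± SD, n = 3 each), a log2 difference of 6.34 (SE 0.66). The gene lies on chromosome 5 from 90903899 to 90905909 (plus strand, build mm10), and its pair differences were 5.02, 5.86 and 8.14. Tnf, a central inflammatory cytokine (chromosome 17, 35199381 to 35202007, minus strand), stood at 165 ± 119 against 27.0 ± 14.6 FPKM (log2 2.44, SE 0.57), and Il1b, the precursor of interleukin-1 beta (chromosome 2, 129364570 to 129375748, minus strand), at 30.7 ± 33.0 against 0.484 ± 0.284 (log2 3.93, SE 0.65). Irg1, which makes the antibacterial metabolite itaconate, stood at 48.5 ± 44.1 against 0.549 ± 0.389 FPKM (log2 4.67, SE 0.58), and Nos2, the inducible nitric oxide synthase, at 27.1 ± 27.3 against 0.241 ± 0.168 (log2 4.07, SE 0.61). By contrast Ctsk and Acp5, the protease and phosphatase that mark osteoclasts, had log2 differences of −0.04 (SE 0.49) and 0.04 (SE 0.50).

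limma without a block called 0 of 9975 genes at a Benjamini-Hochberg adjusted p under 0.05, and 388 had an unadjusted p under 0.05. The same tool with the replicate number as a block called 479 genes, 226 higher and 253 lower in Treat, and 157 of the higher and 119 of the lower ones differed by more than 2-fold. All 479 moved the same way in each of the 3 pairs, as did 45.4% of all genes tested. The blocked fit favours genes whose pairs agree, so this is no separate support for the calls. With only the pair numbered 1 as a block it called 169, of which 168 were among the 479. Of 77 genes taken by the naming rule that passed with the replicate number as a block, 27 did not pass with this one (adjusted p from 0.0538 for Mki67 to 0.316 for mt-Nd2). Among these are Col15a1 (0.156), Ccl9, Oasl1, Bnip3, Tlr13, Lyz2, Itgam, Kif11, Pcna, Fdft1, Cyp51, mt-Nd1, Gpx1, Nfe2l2, G6pdx, Chac1, Atf5, Ppp1r15a, Creld2, Bid, Bcl2l11 and Ago2. After median ratio scaling the blocked fit called 313, 204 higher and 109 lower. Without the block, the groups did not overlap for 810 genes (8.1%, where chance gives 10%), 323 higher and 487 lower in Treat. Leaving out a library called 7 genes without Treat 1 (Csf3, Cxcl2, Ier3, Il1b, Irg1, Ptgs2 and Rsad2), and only Cxcl2 without Treat 3 or without Control 1. The median of all genes lay at −0.12 (log2), and at −0.01 after median ratio scaling, so differences near −0.12 lie at the level of the whole table. Cxcl2 had an adjusted p of 0.0733 without the block and 0.0505 with it.

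Among the other genes with the smallest p, 7 passed with the block. Cd40, a co-stimulatory receptor, rose in the fit with the replicate number as a block by 2.61 (log2; block SE 0.24), Hbegf, an epidermal growth factor receptor ligand, by 3.27 (0.28), and Il1a, the other form of interleukin-1, by 3.24 (0.34). Maff, a small basic leucine zipper factor, rose in that fit by 2.66 (0.30) and Ier3, an immediate early gene, by 2.91 (0.40), as did Irg1 and Nos2. Adjusted p values for these 7 ranged from 0.000396 for Hbegf to 0.0253 for Ier3 with the block and were 0.141 without it. Applying the same naming rule to the blocked fit, a step decided after the fit without a block had called no gene, adds Il1b, Ak4, Ccl4 and Ccl5. Ak4, a mitochondrial adenylate kinase, stood at 31.4 ± 22.1 FPKM in Treat and 2.96 ± 3.08 in Control (log2 3.07, block SE 0.21, adjusted p 0.000112 with the block). Ccl4 and Ccl5, chemokines for monocytes and T cells, rose in the blocked fit by 3.04 (0.20) and 2.98 (0.24).

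The genes with a lower level in Treat that the naming rule took came from several functions. Fli1, an ETS-family transcription factor of blood cells, stood at 4.69 ± 1.92 FPKM in Treat and 15.6 ± 4.03 in Control (log2 −1.57, SE 0.39, n = 3 each). Serpinb12, a serine protease inhibitor, stood at 0.766 ± 0.948 against 5.79 ± 2.43 (log2 −2.01, SE 0.47), and Tpcn1, an endolysosomal cation channel, at 13.8 ± 4.68 against 33.8 ± 3.02 (log2 −1.27, SE 0.34). Both passed with the block, as did Fli1, with adjusted p of 0.00671, 0.00576 and 0.00441. Their adjusted p without it were 0.516, 0.689 and 0.588. St6gal1, a sialyltransferase, Frmd4b, a FERM-domain scaffold, and Ankle1, a nuclease, fell in the blocked fit by 1.31, 1.63 and 1.33. The histone genes Hist1h3g and Hist1h2bh, which lie in 1 cluster on chromosome 13, fell in it by 1.55 and 1.48. Reads of near-identical histone copies can be shared between them. The naming rule on the blocked fit adds Susd3, a sushi-domain membrane protein (log2 −2.40, block SE 0.34), Fam64a, a mitotic regulator (−1.72, 0.36), Col15a1, a collagen (−1.61, 0.24), and Dnhd1, a dynein heavy chain domain protein (−1.59, 0.23).

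**Figure D1:**
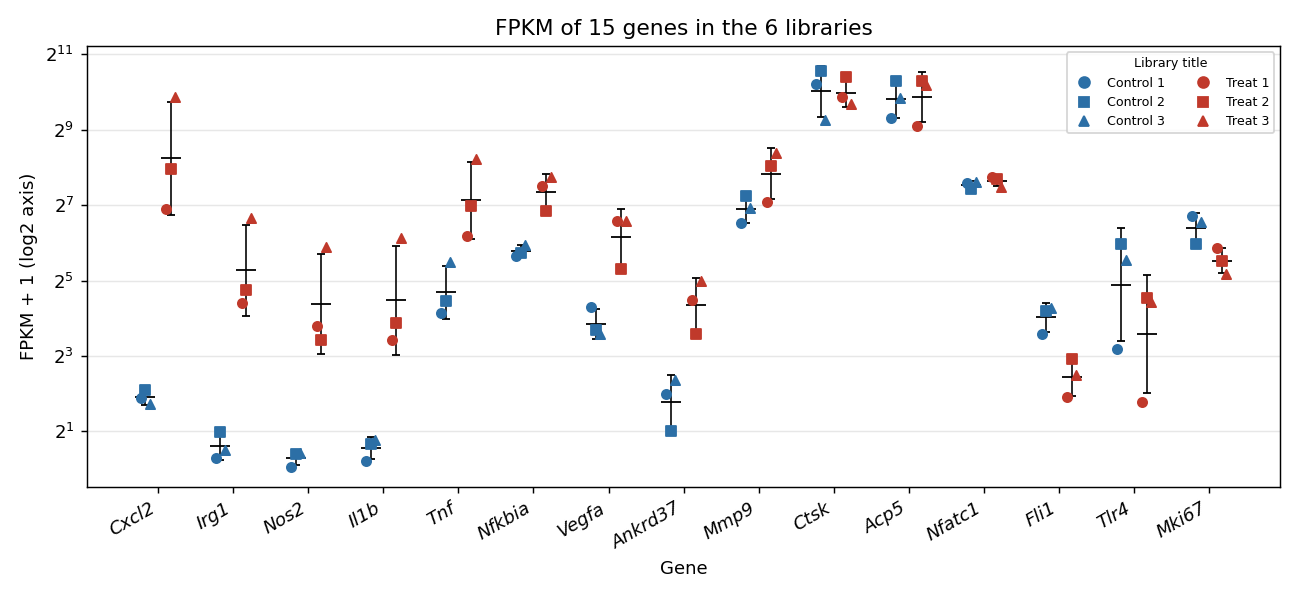
FPKM + 1 on a log2 axis of 15 genes in each of the 6 libraries, with Control in blue and Treat in red and a symbol for each replicate number. The bars are the mean and SD on the log2 scale (n = 3). The Treat libraries of Cxcl2 sit between 119 and 931 FPKM and its Control libraries between 2.30 and 3.30, while the libraries of Ctsk and Acp5 overlap.

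Of the 21 gene lists with at least 3 tested members, 8 passed the camera test with a preset correlation of 0.01, 6 higher and 2 lower in Treat. With an estimated correlation 0 passed, and by fry 0. Other groupings of the same 6 libraries gave up to 12. The list of inflammatory mediators was the farthest from the other genes. All 25 tested members were higher on average in Treat, the groups did not overlap for 21 (10% by chance), and the median log2 difference was 2.199 (2.50 over the libraries numbered 2 and 3; camera adjusted p 4.3e-102). With an estimated correlation its adjusted p was 0.0718. With no block 0 members passed over all genes tested and 22 adjusted over the list alone. With the block 18 rose, 24 adjusted over the list alone, and 0 fell. Ccl3, a macrophage chemokine, stood at 564 ± 234 FPKM in Treat and 107 ± 29.5 in Control (log2 2.33), and Ccl9, the member with the highest level, at 1865 ± 712 against 1287 ± 508 (log2 0.55). Both passed with the block. Ptgs2, the inducible cyclooxygenase, did not, with a log2 difference of 2.99 and an adjusted p of 0.161, and its difference in the pair numbered 1 was 1.48 against 4.76 in the pair numbered 3.

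Targets and parts of the NF-κB pathway, the transcription factor system behind many of those genes, were also higher. Of 33 tested members 32 had higher means in Treat, with a median of 1.11 (1.20 over the libraries numbered 2 and 3; camera adjusted p 2.3e-44; adjusted p 0.149 with an estimated correlation). Adjusted over the list alone 15 passed without a block, and over all genes 0. With the block 23 rose and 0 fell, 27 adjusted over the list alone. Nfkbia, the inhibitor of NF-κB and one of its own targets, stood at 169 ± 50.01 against 54.0 ± 6.25 FPKM (log2 1.59, adjusted p 0.00161 with the block). Nfkbiz, Tnfaip3 and Malt1, regulators of the same pathway, rose in the blocked fit by 2.56, 2.35 and 2.09, and Marcksl1, a MARCKS-related protein, by 1.09. The copies Bcl2a1a, Bcl2a1b and Bcl2a1d on this list are near-identical and can share reads. Rela itself lies in a locus whose estimates failed and was not tested.

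Immediate early genes, the first to respond to a stimulus, had a median of 0.65 over 31 members (0.63 over the libraries numbered 2 and 3), with 25 higher and 6 lower in Treat (camera adjusted p 1.2e-20; adjusted p 0.0779 with an estimated correlation). Over all genes 0 passed without a block, and 7 adjusted over the list alone. With it 10 rose, 15 adjusted over the list alone, and 0 fell. Egr1, a zinc finger factor, stood at 24.8 ± 12.8 FPKM against 2.27 ± 0.471 (log2 2.82), and Dusp5, a phosphatase of the kinase ERK, at 30.9 ± 11.2 against 5.13 ± 1.53 (log2 2.35). Both rose in the blocked fit. Fosl2, an abundant member, had a log2 difference of 0.03. The median was 0.34 in the pair numbered 2 and 0.39 without Control 3.

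Type I interferon genes had a median of 0.81 over 22 members (1.21 over the libraries numbered 2 and 3), but of 0.16 in the pair numbered 1, where 14 of the 22 were higher in Treat against 22 and 21 in the other pairs. It was 1.38 without Treat 1 and 0.46 without Treat 2. The camera adjusted p was 5.3e-17 and the adjusted p with an estimated correlation was 0.252. Without a block 0 passed, and 3 adjusted over the list alone. With the block 4 rose and 0 fell, and 14 passed adjusted over the list alone. The 4 were Rsad2, an antiviral radical SAM enzyme (log2 2.51), Isg15, a ubiquitin-like modifier (2.17), Ifih1, a sensor of viral RNA (1.58), and Oasl1, a translation regulator (1.20). Irgm1, an interferon-inducible GTPase, had a difference of 0.94 (adjusted p 0.149 with the block).

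Genes of glycolysis and of the response to low oxygen were higher as well. Of 28 members 27 had higher means in Treat, with a median of 0.93 (0.90 over the libraries numbered 2 and 3; camera adjusted p 4.3e-32; adjusted p 0.227 with an estimated correlation). No block left 0 past the threshold over all genes, and 10 adjusted over the list alone. With the block 16 rose, 21 adjusted over the list alone, and 0 fell. Those that moved most are classical targets of the hypoxia factor HIF-1. Ankrd37 stood at 20.9 ± 9.82 FPKM in Treat and 2.70 ± 1.58 in Control (log2 2.56), Bnip3, a mitophagy receptor, at 197 ± 160 against 29.97 ± 13.8 (2.49), Pfkfb3, an activator of glycolysis, at 21.05 ± 10.2 against 2.92 ± 0.320 (2.40), and Vegfa, the endothelial growth factor, at 76.1 ± 32.8 against 13.9 ± 4.301 (2.30). The abundant enzymes Pkm and Aldoa had differences of −0.01 and 0.20 and did not pass. The median was 0.57 without Treat 3.

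Cell cycle genes were lower in Treat. Of 31 members 30 had lower means, with a median of −0.69 (−0.69 over the libraries numbered 2 and 3; camera adjusted p 2.4e-10; adjusted p 0.666 with an estimated correlation). The median was −0.73 and −1.36 in the pairs numbered 1 and 3 and −0.04 in the pair numbered 2, and −0.35 without Control 3. Whether over all genes or adjusted over the list alone, 0 passed without a block. With the block 3 fell, 17 adjusted over the list alone, and 0 rose. The 3 were Kif11, a mitotic motor (log2 −0.996), Mki67, the proliferation marker (45.7 ± 10.7 FPKM in Treat, 85.6 ± 21.8 in Control, −0.88), and Pcna, the replication clamp (−0.69). Top2a, a topoisomerase, had a difference of −0.74 (adjusted p 0.0744 with the block). All 19 tested genes of cholesterol synthesis had lower means, with a median of −0.53 (−0.40 over the libraries numbered 2 and 3; camera adjusted p 5.8e-04; adjusted p 0.816 with an estimated correlation), of −0.27 without Treat 1 and of −0.35 without Control 3. In the pairs numbered 1, 2 and 3 the median of this list was −0.57, −0.13 and −0.755, and 6 of the 19 were higher in Treat in the pair numbered 2. Without a block 0 passed on either adjustment. With it 3 fell, among them Fdft1 and Cyp51, enzymes of the pathway, by 1.15 and 0.96, 0 rose, and 5 passed adjusted over the list alone. The abundant member Fdps had a difference of −0.35.

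The osteoclast list moved little as a whole. Its median was 0.05 over 31 members (0.14 over the libraries numbered 2 and 3), with 18 higher and 13 lower in Treat, and its camera adjusted p of 0.0239 became an adjusted p of 0.971 with an estimated correlation. The list did not pass without Treat 2 (median −0.14, camera adjusted p 0.171) or without Control 3 (0.06, 0.294), and its median was 0.34 without Treat 1 and −0.07 without Control 1. Without a block 0 passed on either adjustment. With the block 5 members rose and 1 fell, and 6 rose and 2 fell adjusted over the list alone. Mmp9, a matrix metalloproteinase, stood at 243 ± 101 FPKM against 120 ± 29.5 (log2 0.95, adjusted p 0.0209 with the block). Car2, the carbonic anhydrase that supplies acid for resorption, rose in the blocked fit by 1.11 and Cd44, an adhesion receptor, by 1.13, while Trem2, a DAP12-linked receptor, fell by 1.04. Nfatc1, the main transcription factor of osteoclast formation, and Atp6v0d2, a proton pump subunit needed for cell fusion, had differences of 0.10 and −0.23 with adjusted p of 0.711 and 0.325 with the block. Ctsk stood at 1031 ± 284 FPKM against 1106 ± 457 and Acp5 at 988 ± 384 against 937 ± 315.

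Macrophage genes had a median of −0.30 over 19 members, 16 of them lower in Treat (−0.36 over the libraries numbered 2 and 3). The median turned to 0.11 without Treat 1 and was −0.87 without Control 1, −0.67 without Treat 3, −0.53 without Treat 2, −0.16 without Control 3 and −0.07 without Control 2. The medians without Treat 1 and without Control 1 come from fits that leave the pair numbered 1 unmatched. The list did not pass without the block (camera adjusted p 0.256), passed over the libraries numbered 2 and 3 (0.00133), without Treat 3 (0.00301) and without Control 1 (3.2e-04), and passed with it (0.0147; 0.772 with an estimated correlation and the block). On either adjustment 0 members passed without a block. With it 4 fell, 6 adjusted over the list alone, and 0 rose. Among them were Cx3cr1, the fractalkine receptor (log2 −1.18), Lyz2, lysozyme (−1.06), and Itgam, an integrin (−0.88). Cd68, an abundant lysosomal marker, had a difference of −0.11. Among receptors and adaptors that recognise microbes the median was −0.17 over 25 members (camera adjusted p 0.986), and members went both ways. With the block Tlr4, the receptor for lipopolysaccharide, fell by 1.31, Tlr7 and Tlr13, endosomal receptors for RNA, by 1.13 and 1.03, and Cd36, a scavenger receptor, by 0.95, while Nlrp3, the inflammasome sensor, rose by 1.05. That made 1 higher and 4 lower, against 3 and 5 adjusted over the list alone, and 0 without the block on either adjustment. Cd14, the lipopolysaccharide co-receptor, had a difference of 0.39.

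The remaining lists did not pass camera with or without the block over all 6 libraries, and without the block 0 of their members passed on either adjustment. Lysosomal and proton pump genes had a median of −0.17 over 34 members (camera adjusted p 0.459), where Tfeb, the master regulator of lysosomal genes, and Lipa, the acid lipase, were among 3 that fell in the blocked fit, by 1.29 and 1.18 (5 adjusted over the list alone), and Ctsd and Atp6v1a had differences of −0.47 and −0.18. Autophagy genes had a median of −0.17 and a mean of −0.11 over 27 members, although the camera statistic pointed up (adjusted p 0.986), and 0 passed with the block on either adjustment. Sqstm1, the autophagy receptor p62, had a difference of 0.98 and Gabarap one of −0.18. Genes of oxidative stress defence had a median of −0.30 over 22 members (0.295), where with the block Srxn1, a sulfiredoxin, rose by 1.00, and Gpx1, a glutathione peroxidase, Nfe2l2, which encodes the factor NRF2, and G6pdx, of the pentose phosphate pathway, fell by 0.94, 0.72 and 0.65 (2 higher and 7 lower adjusted over the list alone). The ferritin genes Ftl1 and Fth1 had differences of −0.16 and −0.27. Genes of the unfolded protein and integrated stress responses had a median of −0.03 and a mean of −0.06 over 21 members with a camera statistic that pointed up (0.633). With the block Ppp1r15a and Creld2 rose by 0.92 and 0.78 and Chac1 and Atf5 fell by 1.05 and 0.93, 2 higher and 3 lower in all (5 and 4 adjusted over the list alone). Calr and Hspa5, chaperones, had differences of −0.22 and 0.47.

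Apoptosis genes had a median of −0.12 over 22 members (camera adjusted p 0.823). Bid, Casp9 and Bcl2l11, all promoters of cell death, fell in the blocked fit by 1.17, 0.96 and 0.84, 3 rose and 6 fell adjusted over the list alone, and Mcl1 and Mdm2 had differences of 0.53 and −0.08. Transcripts of the mitochondrial genome had a median of −0.45 over 13 members (0.363). The list passed without Treat 1 (median −0.93, camera adjusted p 0.00169) and without Control 3 (−0.83, 0.0135), and its median was 0.12 without Control 1, −0.05 without Treat 3 and −0.26 without Treat 2. Mitochondrial transcripts made up 5.93% of mRNA fragments in Treat 1 and 6.24% in Control 1, and 1.85% to 2.2% in the others. Without Treat 1 only Control holds such a high library, and without Control 1 only Treat does. Without Control 3 such a library weighs more in Control than in Treat. In these fits a group difference of the list cannot be told from that imbalance. With an estimated correlation the adjusted p of the mitochondrial list over all 6 libraries was 0.816. In it mt-Nd1 and mt-Nd2, subunits of complex I, fell in the blocked fit by 0.50 and 0.45 (3 lower adjusted over the list alone) and mt-Co1, the most abundant, had a difference of 0.23. Nuclear genes of oxidative phosphorylation (33 members, median −0.15, adjusted p 0.633), heat shock genes (10, −0.16, 0.625) and ribosomal protein genes (40, 0.04, 0.363; 0.0235 over the libraries numbered 2 and 3 and 0.0434 without Treat 1; adjusted p 0.971 over all 6 with an estimated correlation) had 0 members that passed with the block on either adjustment. Atp5b and Cox4i1, Hspa8 and Hsp90ab1, and Rplp1 and Rps24 had differences of −0.24, −0.11, −0.26, 0.05, 0.05 and −0.02. Regulators of circRNA formation and decay had a median of −0.21 over 28 members (0.547), where Ago2, an Argonaute, rose in the blocked fit by 0.85 (1 higher and 2 lower adjusted over the list alone) and the splicing-related RNA-binding protein Sfpq had a difference of −0.23. Markers of other cell types were scarce. The stromal list had 0 tested members, the neutrophil list 1 (S100a8, 5.85 ± 5.34 FPKM in Treat and 3.02 ± 2.71 in Control), the lymphocyte list 1 (Lck, 2.198 ± 0.827 and 2.49 ± 0.144), and the dendritic list 3 (camera adjusted p 0.444; 1 lower with the block adjusted over the list alone, 0 over all genes). Cd74 and Itgax of that list had differences of 0.08 and −0.37. None of these lists passed over all 6 libraries. Leaving out Treat 1 or Control 1 unbalances the groups in summed FPKM, as said above, so shifts common to many lists are not particular to any. Most medians turned sign with 1 library left out. Without Control 1 and without Treat 1, the lowest and highest of each list, they were −0.41 and 0.21 for microbial receptors, −0.49 and 0.23 for lysosomal, −0.40 and 0.12 for autophagy, −0.56 and 0.05 for oxidative stress and −0.38 and 0.20 for nuclear oxidative phosphorylation genes. For circRNA regulators they were −0.44 and 0.02, for dendritic genes −0.70 and 0.04, for ribosomal protein genes −0.41 and 0.47 and for apoptosis genes −0.24 and −0.02. The lowest were −0.29 for heat shock and −0.25 for stress response genes, both without Treat 2, and the highest 0.02 without Treat 1 and 0.29 without Control 2. Without Control 2 that of lysosomal genes was 0.05.

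**Figure D2:**
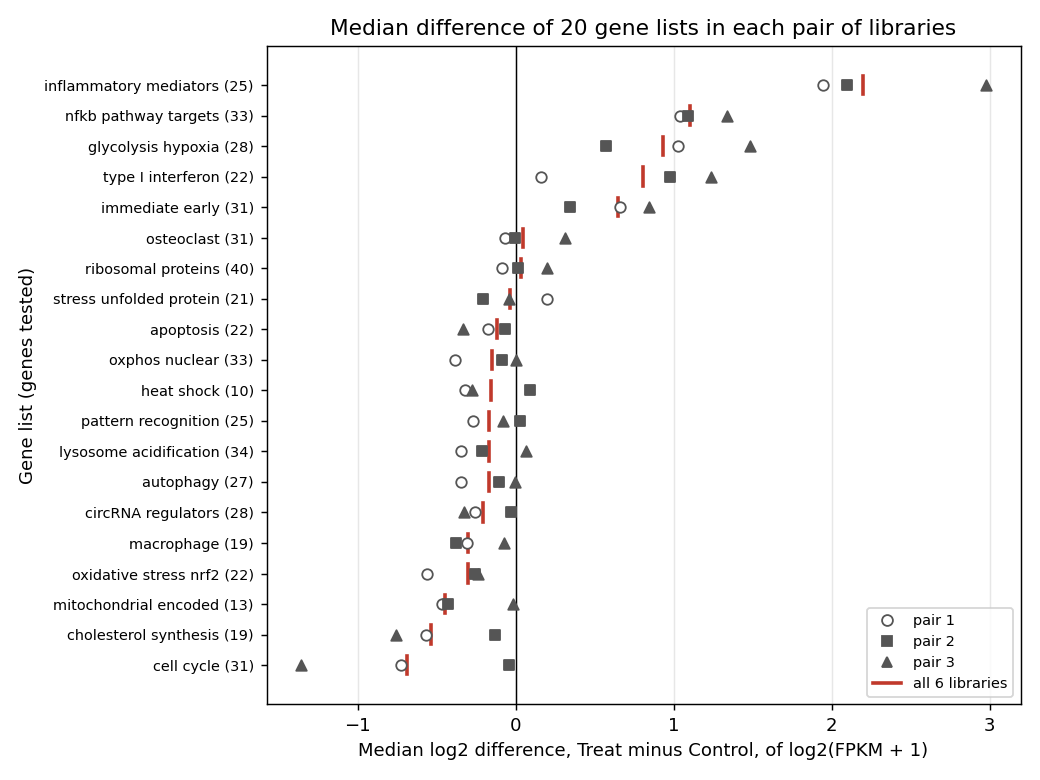
Median log2 difference, Treat minus Control, of 20 gene lists in the pair of libraries numbered 1 (open circles), 2 (squares) and 3 (triangles), with the red bar at the median over all 6 libraries; the number of genes tested stands beside each list. Inflammatory mediators lie at 1.94, 2.09 and 2.98 in the 3 pairs, and the cell cycle list at −0.73, −0.04 and −1.36.

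The lists and the label contradiction can be set side by side. In the pairs numbered 1, 2 and 3, 25, 24 and 25 of the 25 inflammatory mediators were higher in the library titled Treat. Their median difference was 1.94, 2.09 and 2.98, and that of the NF-κB list was 1.04, 1.09 and 1.34. The library with the higher inflammatory genes was in each pair the one whose treatment field calls its cells normal.

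The lncRNAs showed no difference that passed the test. Among the higher ones taken by the naming rule was a transcript of Gp49a, an immunoglobulin-like receptor locus (chromosome 10, 51480632 to 51496613, plus strand), at 19.5 ± 14.5 FPKM in Treat and 2.71 ± 0.925 in Control (log2 2.27, SE 0.61, n = 3 each), which shares exons with the coding genes Gp49a and Lilrb4. AK149231, an intergenic transcript (chromosome 7, 25089321 to 25092182, minus strand), stood at 2.93 ± 1.24 against 0.476 ± 0.127 FPKM (log2 1.37, SE 0.36). AK008812, which shares exons with the phosphofructokinase gene Pfkl (chromosome 10, 77986947 to 78010083, minus strand), stood at 3.58 ± 1.21 against 0.835 ± 0.326 (log2 1.30, SE 0.38). The limma adjusted p was 0.999 for each of the 3, and 0.461 with the block.

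AK211918 shares exons with Tmem120a (chromosome 5, 135735333 to 135744271, minus strand) and had a log2 difference of 1.54, and D19Ertd737e (chromosome 19, 60198586 to 60227678, minus strand) had one of 1.36. Among the lower ones, AK039589, intergenic on chromosome 6 (72162849 to 72167707, plus strand), was listed at 0 in the 3 Treat libraries and at 5.92, 1.70 and 3.25 FPKM in Control 1, 2 and 3. Gm25082, a small RNA that overlaps exons of Clk4, lies in a wider locus on chromosome 11 (51253651 to 51281766, plus strand). It was listed at 0 in Treat and at 2.85, 5.63 and 0.932 FPKM in Control. Gm6525, in an intron of Trim2 on the other strand (locus on chromosome 3, 84160439 to 84306877), was listed at 0 in Treat and at 2.202, 0.864 and 1.16 FPKM in Control. Transcripts that share exons with the cell cycle inhibitor Cdkn2c and the kinase gene Csnk1e had log2 differences of −1.60 and −1.29. Their loci are on chromosome 4 (109660876 to 109668249, minus strand) and chromosome 15 (79166041 to 79867219, minus strand).

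limma called 0 of 2867 lncRNA units, with 90 at an unadjusted p under 0.05, and 0 with the replicate number as a block, with 291. Leaving out Treat 1 called 1, a transcript of NADH-cytochrome b5 reductase (log2 4.20), and leaving out Control 1 called 3, 2310009A05Rik, AK181773 and a transcript of Sf3b3 (−3.97, −3.95 and −2.85). The libraries numbered 2 and 3 alone called 2, the same reductase transcript and AK181773. Of 45 known lncRNAs listed beforehand 17 were tested and 0 passed, with or without the block. Gas5, the host of many small nucleolar RNAs, stood at 266 ± 86.3 FPKM in Treat and 189 ± 120 in Control, and Pvt1 at 18.3 ± 12.5 against 12.9 ± 9.61. Malat1 and Neat1 were listed at 0 in Treat 2, Treat 3 and Control 2 because of the failed locus and are not compared.

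No circRNA passed the test either. Among the higher ones the smallest p belonged to a circRNA of Tcf20, a transcriptional coregulator (mmu_circ_0000629, chromosome 15, 82851513 to 82857284, minus strand, exonic), with 4, 37 and 64 junction reads in Treat 1, 2 and 3 and 4, 31 and 36 in Control 1, 2 and 3 (log2 0.81, SE 0.50, n = 3 each, edgeR adjusted p 0.962). The exonic circRNA of Tns3, a focal adhesion protein (mmu_circ_0000233, chromosome 11, 8478225 to 8479665, minus strand), had 0, 19 and 24 against 1, 5 and 15 reads (log2 1.17, SE 0.93). The lower circRNA with the smallest p spanned 62708 bases and is listed under Hfe, the haemochromatosis gene (mmu_circ_0004534, chromosome 13, 23698387 to 23761094, minus strand), with 0, 31 and 65 reads in Treat and 7, 65 and 115 in Control (log2 −0.77, SE 0.44). Its ends lie inside Hist1h4c and Hist1h4a, histone H4 genes on the same strand whose near-identical copies can share reads, so that its place is uncertain, and both had lower means in Treat (−0.78 and −0.72). An exonic circRNA of the osteoclast factor Nfatc1 (chromosome 18, 80697555 to 80698656, minus strand) had 5, 21 and 21 against 9, 27 and 40 reads (log2 −0.39, SE 0.58).

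The naming rule also took 3 higher and 3 lower circRNAs. The higher ones were 2 of Spred1 on chromosome 2, from 117152992 to 117164995 and to 117172086 (plus strand, log2 0.99 and 0.64), and 1 of Zfp609 on chromosome 9 (65794622 to 65795495, minus strand, 0.73). Zfp609 had 8 of its reads in Treat 1 and a difference of −0.36 over the libraries numbered 2 and 3. The lower ones were those of Whsc1 (chromosome 5, 33843112 to 33846267, plus strand, −0.46), Zfp644 (chromosome 5, 106634831 to 106638635, minus strand, −0.77) and, in an intron, Ahnak (chromosome 19, 9006380 to 9006580, plus strand, −0.78).

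The quasi-likelihood test of edgeR called 0 of 27 circRNAs, the number with enough reads, with 0 at an unadjusted p under 0.05. DESeq2 called 0. Over the libraries numbered 2 and 3 edgeR called 0 of 58, with 1 at an unadjusted p under 0.05. All circRNAs together had 4221 to 7188 junction reads per library. Those in exons numbered 480 in Treat 1 and 702 in Control 1, against 3996 to 5719 in the libraries numbered 2 and 3, so the pair numbered 1 adds little to this comparison. In simulated counts of this depth a difference of 1 (log2) was found for 7.5% of the changed circRNAs, one of 2 for 40.0% and one of 3 for 75.0%. How far depth limited the calls was not tested apart.

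The circRNA table listed 11522 circRNAs, of which 85.6% had reads in 1 library and 29 in all 6. Exonic circRNAs numbered 4268, those overlapping a gene in sense 4500, intronic ones 2314, intergenic ones 336 and antisense ones 104. The number detected per library differed between the groups by less than the spread between libraries, with 2246 ± 948 circRNAs per Treat library and 2504 ± 1161 per Control library (difference −257.7, exact two-sided permutation p 0.6, where 0.1 is the smallest possible). Over the libraries numbered 2 and 3 the difference was −145.0 (exact permutation p 0.667). It was 58.0 without Treat 2 and 399.8 without Control 1. Exonic junction reads per 1000000 mRNA fragments came to 220 ± 8.3 in Treat and 235 ± 21.8 in Control (exact permutation p 0.3, n = 3 each).

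The junctions listed as circRNAs in the libraries numbered 1 were of other kinds than in the rest. Junctions in the 45S ribosomal RNA repeat on chromosome 17, between 39843003 and 39848719, made up 59.7% of the junction reads in Treat 1 (95% Wilson interval 58.2 to 61.2) and 57.6% in Control 1 (56.3 to 58.9). In Treat 2 and 3 they made up 0.40% (0.26 to 0.61) and 0.03% (0.01 to 0.11), and in Control 2 and 3 0.10% (0.05 to 0.20) and 0.14% (0.07 to 0.27). Exonic junctions held 11.4% of the reads in Treat 1 (10.5 to 12.4) and 13.0% in Control 1 (12.1 to 13.9), against 76.9% to 79.6% in the other 4. These intervals cover counting error only. Of the listed circRNAs, 81.5% in Treat 1 and 71.4% in Control 1 had a single read, against 10.1% to 15.3% elsewhere. Those with a catalogue identifier made up 7.7% and 8.5%, against 56.8% to 59.7% elsewhere. Exonic reads scaled to mRNA fragments as above were 227.1 in Treat 1 and 236.5 in Control 1, and 210.7 to 256.2 elsewhere. Whether the junctions in the repeat come from circular RNA was not tested.

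**Figure D3:**
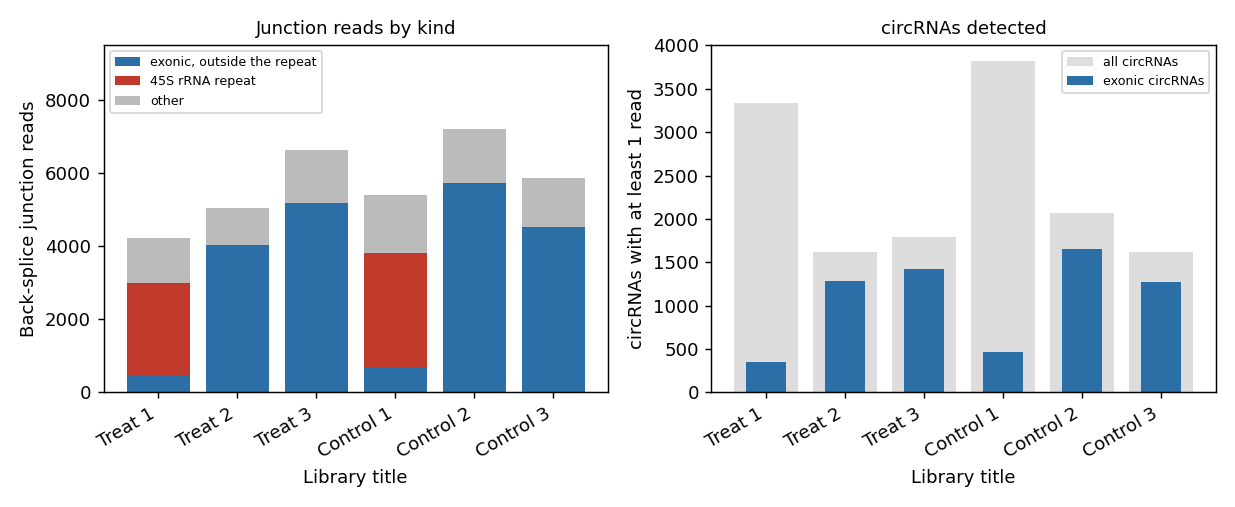
Left, back-splice junction reads in each of the 6 libraries, stacked by kind (exonic outside the repeat, in the 45S ribosomal RNA repeat, other); right, the number of circRNAs with at least 1 read (grey) and of exonic ones (blue). Treat 1 and Control 1 are listed with 3336 and 3819 circRNAs, of which 353 and 462 are exonic.

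The last comparison was between circRNAs and their host genes. Across the 27 tested circRNAs, which are not independent replicates, the log2 differences of circRNA and host gene had a Pearson r of 0.37 and a Spearman rho of 0.23, and 12 pairs had the same sign. One of them is catalogued as antisense to Epha5, a gene listed at 0 in all 6 libraries, and was entered with a host difference of 0. Without it r was 0.38 across 26. The 12 include the junction listed under Hfe, whose ends lie in histone genes. It had the lowest host difference of the 27 (−1.03, with −0.77 for the circRNA), and r without it was not computed. Over the libraries numbered 2 and 3 the r was 0.23 across 57 circRNAs. Among the 9 found in all 6 libraries whose host passed the mRNA filter it was 0.03, with a Spearman rho of −0.35, and 1 of the 9 had the same sign in both. The circRNA of Tns3 had a difference of 1.17 while Tns3 mRNA had one of −0.14, at 99.8 FPKM in Treat and 107 in Control.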

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

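Blocks on the pair numbered 1, transcript classes left out, library weights, combined settings, the libraries numbered 2 and 3 alone, single pairs, the failed locus kept, sums over host genes, hosts listed above 0 and the removal of the ribosomal repeat were chosen after the data were seen. The other alternatives were planned. limma called 0 mRNA genes with pseudocounts of 0.1 and 0.01, without a filter, with a filter 5 times stricter, without trend or robust moderation, line by line, and with the failed locus kept (250 to 616 at an unadjusted p under 0.05 in these), and over the libraries numbered 2 and 3 (963 at an unadjusted p under 0.05). It called 3 with quantile normalization and 3 with median ratio scaling (Cxcl2, Irg1 and Ptpre in both). The replicate block gave 479. Blocking only the pair numbered 1 gave 169 (113 higher, 56 lower; 168 among the 479), median ratio scaling with the replicate block 313 (299 shared), quantile normalization with it 248 (167 higher, 81 lower; 239 shared), a pseudocount of 0.1 with it 410 (405 shared), and median ratio scaling with the block on the pair numbered 1 145 (114 higher, 31 lower). Library weights gave 2211 (909 higher, 1302 lower; 452 of the 479 shared). Leaving out 1 library gave 0 to 7 genes, with 7 without Treat 1, 1 without Treat 3 and 1 without Control 1. The block takes differences between pairs out of the spread. For the other settings the cause was not tested.

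The lncRNA count was 0 under the planned settings with all 6 libraries, the replicate block included, 2 over the libraries numbered 2 and 3, and 0 to 3 with 1 library left out (1 without Treat 1, 3 without Control 1). The circRNA count was 0 in every alternative run, with DESeq2, without a filter among 11522 (15 at an unadjusted p under 0.05), with a stricter filter among 3, with junction reads summed over 58 host genes, with the replicate block (2 at an unadjusted p under 0.05) and with each library left out. Correlations of its numbered pairs were 0.46, −0.054 and 0.567, and with the pair numbered 2 under 0.1 the libraries share only a number there. Control 2 correlated best with Treat 3 (0.158). Pseudocounts, quantile normalization and limma without trend were not run on circRNA counts, which they do not apply to. Camera called 8 lists, 9 with the replicate block, 9 with the block on the pair numbered 1, 10 over the libraries numbered 2 and 3, 7 to 10 with 1 library left out, 0 with an estimated correlation, 0 by fry and 0 with an estimated correlation and the replicate block. Beyond those printed in the report the block changed no call of a list or lncRNA.

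The difference in detected circRNAs was −254.0 for those with at least 2 reads, −196.0 outside the ribosomal repeat, and −802.5 to 399.8 with 1 library left out (58.0 without Treat 2), so its sign rests on single libraries. The Pearson r of circRNA and host differences ran from 0.299 to 0.425 with 1 library left out and was 0.031 among the 9 circRNAs in all 6 libraries with a host past the mRNA filter. The median of the inflammatory list was 3.145 with a pseudocount of 0.1 and 2.977 in the pair numbered 3, that of the NF-κB list 1.335 in the pair numbered 3, and that of the immediate early list 0.343 in the pair numbered 2; the cause was not tested. Of 113 named mRNA genes 77 passed with the replicate block, 51 with the block on the pair numbered 1, and 25 had the opposite sign in some setting, though none passed there. Of these 4 had passed with the block: Cd36 (0.53) and Lyz2 (0.47) without Treat 1, mt-Nd1 (0.12) and mt-Nd2 (0.30) without Control 1, and mt-Nd2 (0.10) without Treat 3. The filter on reads left 27 circRNAs to test, and how far the few junction reads limited the calls among these was not tested.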

Other observations

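The tests of histone genes, KEGG pathways, explanations and splits were chosen after the result was seen, except that of the exonic circRNA overlap, while the fits with the replicate number as a block, without it and with other scalings were planned. Histone genes were lower in the libraries titled Treat. Of 64 tested genes whose symbols begin with Hist and a number, 62 were lower, with a median log2 difference of −0.84 (−0.71 after median ratio scaling and −0.74 after quantile normalization, where 61 were lower). The groups did not overlap for 17 (10% by chance), all lower in Treat, and 25 fell in the fit with the replicate number as a block while 0 rose. With only the pair numbered 1 as a block not all of the 25 passed, Hist2h3c1 among those lost (limma adjusted p 0.122). Hist1h1a, a linker histone, stood at 81.9 FPKM in Treat and 190 in Control. The median was −1.04, −0.25 and −1.21 in the pairs numbered 1, 2 and 3. Copies of these genes can share fragments. Of 238 KEGG pathways 44 ranked higher and 4 lower than the other genes by camera at the preset correlation, with 45 and 5 under the block. An estimated correlation was not run for them. The lower ones were those of systemic lupus erythematosus (80 genes, of which 59 are histone genes, median −0.75, adjusted p 1.1e-08), alcoholism (121 genes, −0.43, adjusted p 1.9e-05), the cell cycle (112 genes, −0.29) and DNA replication (33 genes, −0.46). The higher ones began with cytokine receptor interaction (89 genes, median 0.16, adjusted p 1.4e-17) and NF-κB signalling (71 genes, 0.16, adjusted p 1.4e-14). Since the median of all genes lay at −0.12, a pathway that ranked higher can have a median under 0. Such were Salmonella infection (58 genes, −0.07) and Toll-like receptor signalling (72 genes, −0.045), among others.

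Genes outside the lists that passed with the block, chosen after their values were seen, included Hilpda, Adm, Pgf and Eno2. Hilpda, a lipid droplet protein, stood at 158 ± 151 FPKM in Treat and 20.5 ± 11.2 in Control (log2 2.58), Adm, the vasodilator adrenomedullin, at 23.2 ± 16.5 against 2.61 ± 0.734 (2.34), Pgf, a placental growth factor, at 13.0 ± 15.6 against 0.727 ± 0.482 (2.45), and Eno2, an enolase, at 41.2 ± 27.6 against 9.83 ± 0.966 (1.76). Cd274, the immune checkpoint ligand PD-L1, rose in that fit by 1.56, Serpinb6b, a protease inhibitor, by 1.91 and Phlda1, with a pleckstrin homology-like domain, by 2.13. Rgs2, which shortens G protein signals, fell by 1.83 (50.6 ± 39.7 against 167 ± 91.8 FPKM), Sirpa, an inhibitory receptor of macrophages, by 1.45, Alox5ap, the helper of 5-lipoxygenase, by 1.44 and H2-DMa, which loads peptides on MHC class II, by 1.34. The libraries of the groups overlapped for Rgs2, Sirpa and Alox5ap. With only the pair numbered 1 as a block Adm, Pgf, Eno2 and H2-DMa did not pass (adjusted p 0.143, 0.0878, 0.0674 and 0.117). Ptpre, a receptor-type phosphatase, also passed without a block after quantile normalization and after median ratio scaling, at 14.4 ± 4.38 FPKM in Treat and 3.05 ± 0.991 in Control.

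The inflammatory genes were higher in the libraries titled Treat, whose treatment field calls the cells normal. The lowest pair medians were 1.943 for the inflammatory list and 1.04 for the NF-κB list, so if the field is right these genes were lower in the infected cells. Shallow sequencing of the pair numbered 1 is argued against by a median of 2.495 for the inflammatory list over the libraries numbered 2 and 3. A treatment field swapped between the groups, and a right field with these genes lower after infection or raised by another stimulus, cannot be told apart, because the values that bear on it are those that showed the pattern and no bacterial reads were used here.

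Treat 1 and Control 1 shared few circRNAs with the later libraries, 6.1% to 8.6% of the smaller list against 29.4% to 33.4% among the 4 later ones, and 8.1% with each other. A lower total of junction reads as the whole cause is argued against. The totals differed little (4221 in Treat 1 and 5401 in Control 1, against 5041 to 7188 later), and exonic reads (480 and 702) were not matched. Later libraries thinned to the totals of Treat 1 or Control 1 still held 22.7% or more of another later list. The lowest gap to the observed percent was 16.6 percentage points for these later libraries. Fewer mRNA fragments, as inferred, stay open, since at that depth they held on average 8.3% to 12.8%, and the lowest thinning exceeded the observed percent by 0.9 to 2.1 points, less than the range of the thinnings (2.9 to 4.6). Junctions outside exons fill these lists, and 0.7% and 0.9% of them recurred in later libraries. Of the exonic circRNAs of Treat 1 and Control 1 41.6% and 37.4% recurred, against 56.4% and 55.3% for thinned later libraries (lowest 49.8% and 48.5%). The differences were −14.8 and −17.9 percentage points. Whether such junctions are the whole cause cannot be told from this, because the later lists hold few circRNAs with a single read. These made up 10.1% to 15.3% of all circRNAs there, against 81.5% and 71.4% in Treat 1 and Control 1, so thinning started from lists of another kind. A difference in library making between the pair numbered 1 and the rest may contribute and was not tested, and no biological explanation was tested, since both groups have 1 such library.

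The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For mRNA without a block 10 of 10 splits gave as many genes (real value 0, highest other 0), for lncRNA 10 of 10 (0 and 1) and for circRNAs 10 of 10 (0 and 1). Of the 4 splits that part every pair, 1, the real one, gave as many mRNA genes with the replicate number as a block (real value 479, highest other 0); the others exchange the titles within 1 pair, and 4 splits are again too few. For gene lists 6 of 10 splits gave as many (real value 8, highest other 12). The split with 12 put Treat 1, Control 1 and Control 3 together, so both libraries numbered 1 were on 1 side; camera with the replicate number as a block gave 9 lists. The splits other than the real one that part every pair gave 10, 11 and 6. The 4 splits that put both libraries numbered 1 on 1 side had 1201 to 2782 mRNA genes at an unadjusted p under 0.05 by limma, against 388 for the real split, which points to a structure of the samples along that pair.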
